A study of Homo sapiens with 23 samples.

How the data were processed

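Gene expression was measured on single-colour Illumina bead arrays in CCL-75 cells, an established line of human lung fibroblasts. The 23 arrays fall into 6 groups: untreated cells (Control, 4 arrays), cells given IL-13 for 20 hours (IL13, 4), cells given TNF and IL-17 for 72 hours (Pre_only, 3), pretreated cells then given IL-13 (Pre_IL13, 4), pretreated cells given a neutralising antibody to IL-13Ra2 for the last 1 hour (Pre_Ab_only, 4), and pretreated cells given the antibody, washed and given IL-13 (Pre_Ab_IL13, 4). Cells came from passage 6 and passage 8, with experiments A and B in each, and arrays are named by passage and experiment (P6-A). Pre_only holds 1 array of passage 8, P8-B. Each passage was hybridised on its own beadchip, so passage and beadchip cannot be told apart. RNA was amplified from 300 ng of total RNA with biotin labelling.

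The deposited scanner table holds the mean bead intensity of 47323 probes per array, which the authors exported from GenomeStudio 2011.1 without normalisation. Per the file headers, a detection p-value from 0 to 1 stands beside each intensity. The authors' table of normalised values holds 31390 probes on a log2 scale. Its columns share nearly the same sorted values, between 6.35 and 14.2, and each follows the log2 intensity of its array with a correlation of 0.997 or more, so it was taken as quantile normalised without background subtraction. It was used only as an alternative. Intensities in the scanner table and in the per-array files differed in 0 values. No genome build came with the files, so no positions are given, and a RefSeq gene table (assembly GRCh38.p14), in which 21309 probes were found by gene ID, was used only for symbols and for which genes neighbour each other.

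Intensities were background-corrected and normalised with the neqc function of limma 3.58.1 in R 4.3.3, which fits a normal-exponential model with negative controls inferred from detection p, adds an offset of 16 and applies quantile normalisation. The 14 probes without a value on some array were left out of the normalisation and all tests. Probes with a detection p under 0.05 on at least 3 arrays were kept (24109, with 13 of those 14 counted), and gene symbols came from the probe annotation of the authors' table: 21332 of its probes have 1 symbol, 7 have several and 10051 have none. The 6561 kept probes without a single symbol were left out of the gene comparisons, and 6 of them are among the 14 without a value on some array. For each gene the probe with the highest mean intensity was used, which gave 12994 genes. Level means log2 normalised intensity throughout. A gene with detection p of 0.05 or more on every array of a group is called undetected there, and its fold was then computed with its values in that group raised to the lowest level of any detected probe on each array, and is written as "at least".

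A linear model with a term for each group and a term for passage was fitted to each gene over all 23 arrays with limma (lmFit, then eBayes with an intensity trend), which left 16 residual degrees of freedom. In all, 9 comparisons were tested: 6 between groups and 3 differences between responses to IL-13. Within each, p-values were adjusted with the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. Error after a log2 change is the standard error (SE) of the model; group levels carry the standard deviation (SD). Passage-specific values are differences of group means within a passage.

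The named genes were fixed by a rule: in each comparison, the called genes with the largest change in each direction and the same sign in both passages (10 and 10 for IL-13 without pretreatment and for pretreatment, 8 and 8 for the other IL-13 responses and the antibody with IL-13, 5 and 5 elsewhere), up to 4 called members of each described gene list, and always IL13RA2, IL13RA1, IL4R, STAT6, SOCS1, CCL26, CCL11 and POSTN. Provisional symbols were passed over, and 1 gene that the rule chose is not reported here. A total of 22 gene lists were written before the data were examined, as were the groups, tests and alternatives. They were tested with camera (limma) at a preset correlation of 0.01 between genes and adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Counts of called members are given over all genes and adjusted over the list alone. The score of IL-13 and IL-4 induced genes is the mean level of the list's 13 tested members, compared with two-sided exact permutation tests. Genes that respond to IL-13 were also chosen in 1 passage, at an adjusted p under 0.05 and at least 1.5-fold, and measured in the other.

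The alternatives changed the background correction, the normalisation, the source of the values, the detection filter, the choice of probes, the passage term, the replicate unit, the arrays included, the array weights, the minimum fold, the adjustment, the gene list test and the selection of responsive genes; each array was left out in turn. Leaving out both IL13 arrays of passage 6 was added after the data had been seen, because the standard error of the beads within a probe was 5.46% and 5.31% of the mean there and at most 3.64% on the others. The fit was tested on simulated data with 200 changed genes: in the comparison of IL13 with Control it recovered 79.1% of changes of 1.5-fold, all those of 2-fold and 4-fold, and called 9 unchanged genes, and for the change of the IL-13 response by pretreatment it recovered 43.3% at 1.5-fold and 83.6% at 2-fold. The simulated noise was independent between genes and between arrays, so these shares do not cover residuals that vary together. The number of detected probes ran from 17818 to 20167 per array. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.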

Results

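Expression of 12994 genes was compared on 23 arrays of CCL-75 human lung fibroblasts, which were given IL-13, a cytokine of type 2 immunity. Some had first received TNF and IL-17, with or without an antibody to IL-13Ra2. IL-13Ra2, encoded by IL13RA2, binds IL-13 and is known as a decoy receptor. Control, IL13, Pre_IL13, Pre_Ab_only and Pre_Ab_IL13 each hold 4 arrays and Pre_only holds 3. Between 17818 and 20167 probes were detected per array, and median intensities before normalisation ran from 93.4 to 106. The IL13 arrays of passage 6 had the least even beads: the standard error within a probe was 5.46% of its mean on P6-A and 5.31% on P6-B, against 3.14% on the most even array. The leading principal component held 52.1% of the variance, and pretreatment accounted for 98.9% of it. The next held 11.1%, of which passage accounted for 91.3%, and 3820 genes differed between the passages.

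**Figure D1:**
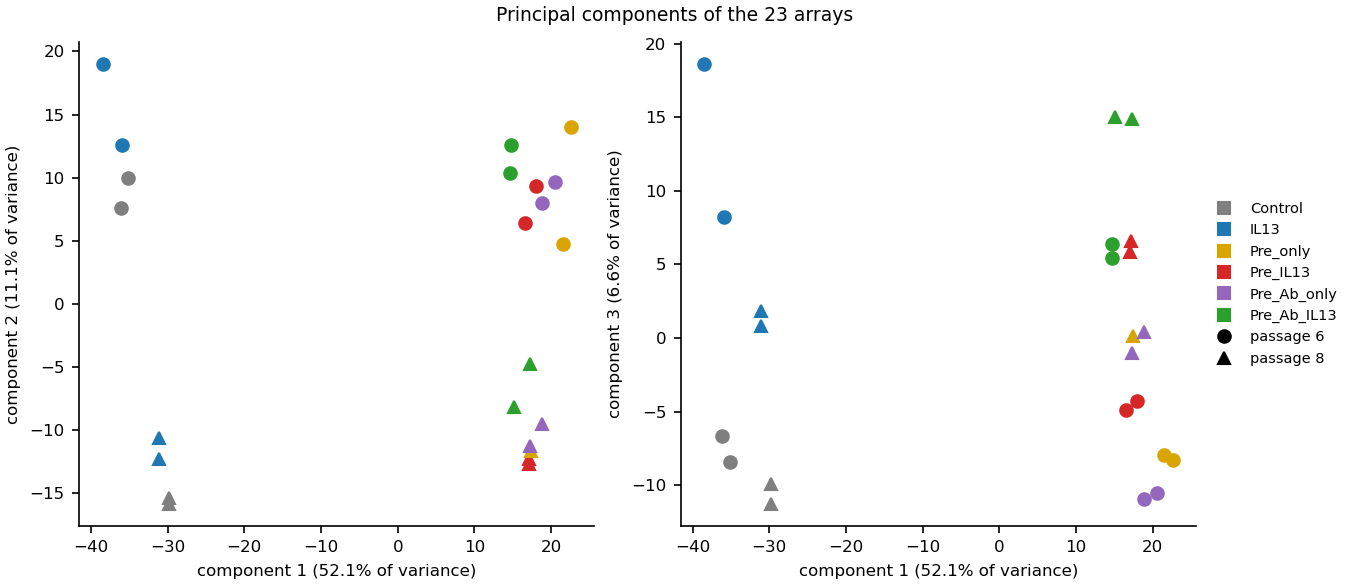
Scores of the 23 arrays on principal components 1 and 2 (left) and 1 and 3 (right) of the log2 levels, coloured by group, with circles for passage 6 and triangles for passage 8. Component 1, with 52.1% of the variance, separates all pretreated from all other arrays, and component 3, with 6.62%, places the IL13 above the Control arrays within each passage.

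The comparison of IL13 with Control asked which genes IL-13 changes in fibroblasts that had not been pretreated. CCL26, which encodes the eosinophil chemokine eotaxin-3, rose 32.4-fold (log2 change 5.02 ± 0.20, SE, n = 4 and 4, adjusted p = 1.67e-17), by 5.03 in passage 6 and 5.01 in passage 8. CCL11, which encodes eotaxin-1, was undetected on all 4 Control arrays and was at least 9.52-fold higher with IL-13, with a log2 change of 4.59 in passage 6 and 2.53 in passage 8. INHBE, an inhibin subunit, rose by 2.26 ± 0.23 and ST8SIA1, a ganglioside sialyltransferase, by 2.01 ± 0.16. LRRC8B, a subunit of volume-regulated anion channels, rose by 1.91 ± 0.16 and ANPEP, aminopeptidase N, by 1.89 ± 0.16. CFAP300 (1.83), the transcription factor BATF3 (1.70), PTGIS, which makes prostacyclin (1.64), and C1QTNF1 (1.59) completed the 10 largest rises. The falls were smaller: KISS1, which encodes kisspeptin, changed by -1.07 ± 0.18, the tight junction gene CLDN1 by -0.95 ± 0.11 and TRIM55 by -0.89 ± 0.13. The matrix protease ADAMTS1 (-0.86 ± 0.10) and the autophagy gene DRAM1 (-0.84 ± 0.11) followed. TENT5C, LCE2C, KCNF1, EDN1 (endothelin-1) and IGFBP3 changed by -0.86 to -0.80.

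Of the 13 tested IL-13 and IL-4 induced genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 7.43e-18, and 8.12e-05 with an estimated correlation). Besides both eotaxins these included POSTN, which encodes the matrix protein periostin (1.21 ± 0.20), SOCS1, an inhibitor of cytokine signalling (1.15 ± 0.10), and IL13RA2 itself (1.03 ± 0.14). In the IL-13 receptor and STAT6 pathway 3 of 18 genes rose and 2 fell (4 and 2 over the list alone), among them CISH, another inhibitor of cytokine signalling (0.66 ± 0.13), and the adaptor IRS2 (-0.64 ± 0.14). This list did not pass the test (adjusted p = 0.147). The signalling receptor genes IL13RA1 (-0.10 ± 0.10, adjusted p = 0.75) and IL4R (0.16 ± 0.11, adjusted p = 0.615) and the transcription factor gene STAT6 (-0.18 ± 0.10, adjusted p = 0.504) were not called.

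Of 27 cell cycle genes, 5 fell and 0 rose (10 and 0 over the list alone; adjusted p = 7.51e-09, and adjusted p = 0.0728 with an estimated correlation). UBE2C (-0.71) and CDC20 (-0.68), both of the anaphase-promoting complex, and TPX2 (-0.58), a spindle gene, were among them. In the extracellular matrix list 5 of 31 genes rose (7 over the list alone, with 1 fall), including TNC, tenascin C (0.98 ± 0.14), COL6A2 (0.63) and LOX, a collagen cross-linking enzyme (0.60). The matrix list had an adjusted p = 1.08e-04, and adjusted p = 0.293 with an estimated correlation. Of 28 TNF and NF-kB induced genes 4 rose (5 over the list alone, with 1 fall). They were the monocyte chemokines CCL7 (1.52 ± 0.19) and CCL2 (1.02 ± 0.09), TRAF1 (0.88) and the adhesion molecule VCAM1 (0.69). The list had an adjusted p = 0.0163, and adjusted p = 0.293 with an estimated correlation. In the prostaglandin pathway PTGIS and the receptor PTGER4 (0.69) were the 2 of 15 genes that rose, on either adjustment (adjusted p = 0.0148, and adjusted p = 0.131 with an estimated correlation). ATF3, a stress-induced transcription factor (1.30 ± 0.21), was the 1 unfolded protein response gene of 21 that rose. Over the list alone 4 rose (adjusted p = 9.66e-04, and adjusted p = 0.293 with an estimated correlation). The metallothioneins MT1M (-0.66) and MT1X (-0.44) fell and GCLM (0.51), of glutathione synthesis, rose in the oxidative stress and metallothionein list of 20. Over the list alone 4 fell and 1 rose (adjusted p = 0.0196, and adjusted p = 0.295 with an estimated correlation). The 2 tested endothelial markers, TEK (-0.46) and VWF (-0.46), both fell, on either adjustment (adjusted p = 0.00104, and 0.0303 with an estimated correlation). IL6 rose (1.37 ± 0.29) among 19 IL-17 induced genes (4 over the list alone), a list that did not pass (adjusted p = 0.187).

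In total 243 genes were called, 150 of which rose and 93 fell. All 243 had the same sign in both passages, and 29 changed at least 2-fold. With passage 6 alone 234 genes were called and with passage 8 alone 146. The count was 97 without both IL13 arrays of passage 6, 113 with the passage term left out, 92 with median scaling and 55 with the mean of A and B. Leaving out 1 array ended the calls of TENT5C, KCNF1, EDN1, IGFBP3, IRS2, IL6, CDC20, TPX2, MT1M, MT1X, TEK and VWF.

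**Figure D2:**
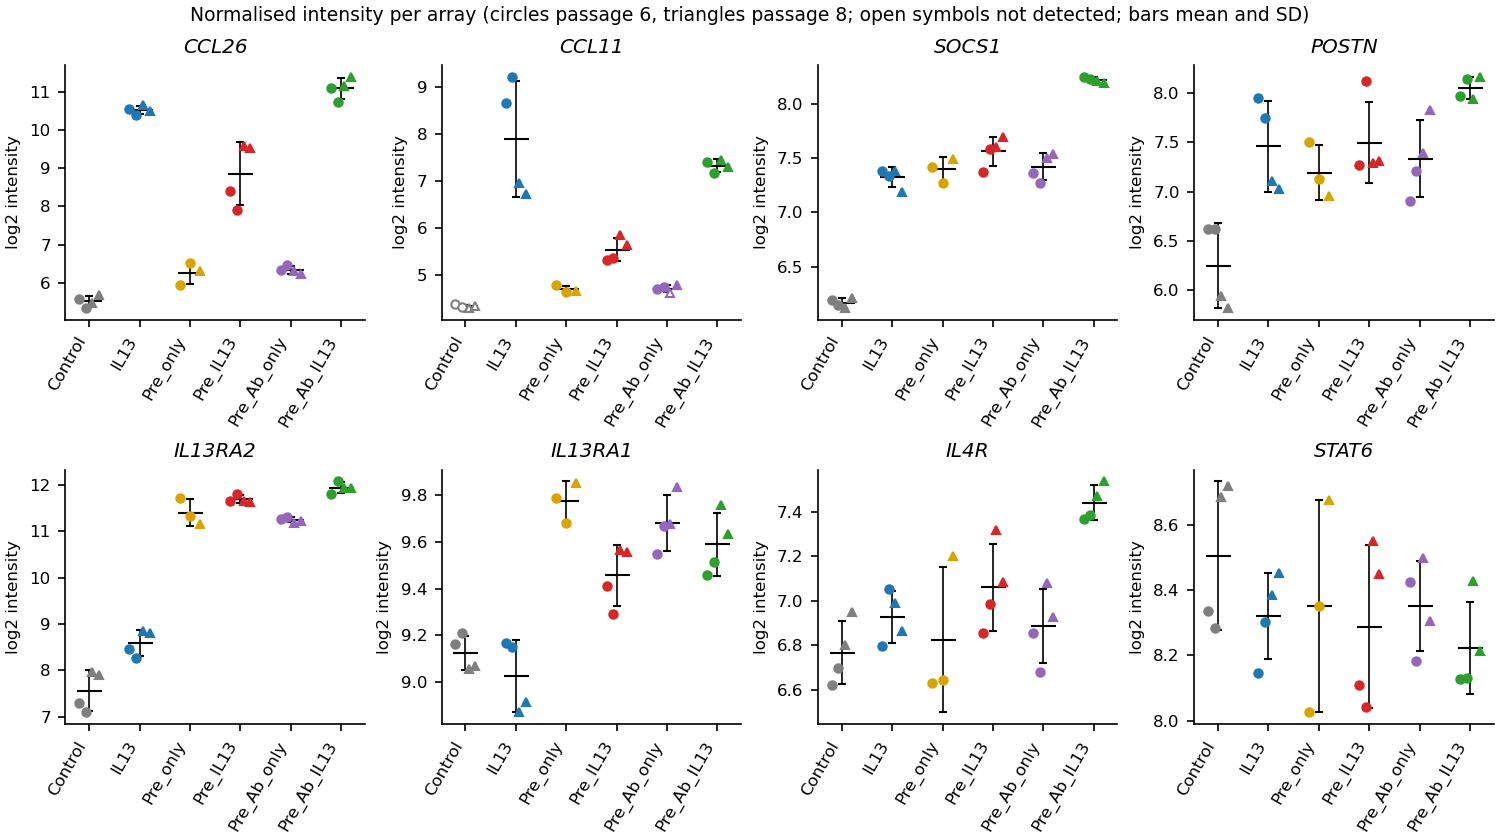
Log2 normalised intensity of 8 genes on each array by group, with circles for passage 6, triangles for passage 8 and open symbols where the gene was not detected; black bars give the group mean and SD. CCL26 has a mean of 5.51 in Control, 10.53 in IL13, 6.26 in Pre_only, 8.86 in Pre_IL13, 6.33 in Pre_Ab_only and 11.10 in Pre_Ab_IL13, while IL13RA2 stands above 11 on every pretreated array.

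Pre_only against Control showed what 72 hours of TNF and IL-17 did before any IL-13 was given. Neutrophil chemokines rose most: CXCL6 by 8.78 ± 0.18 and CXCL1 by 7.47 ± 0.18 (each detected on 2 of 4 Control arrays). CXCL5 rose at least 289-fold from undetected levels and CXCL8, which encodes interleukin-8, by 6.30 ± 0.24 (n = 3 and 4, adjusted p = 2.78e-19). CCL5, a T cell and monocyte chemokine, rose by 5.95 ± 0.11, CCL20 at least 40.4-fold from undetected levels, and CCL8 by 5.12 ± 0.16. KYNU, kynureninase (4.86), COXFA4L3 (4.64) and the mitochondrial carrier SLC25A24 (4.60) followed. IL13RA2 rose 14.5-fold (3.85 ± 0.15, adjusted p = 1.43e-18), from a level of 7.56 ± 0.44 (SD) in Control to 11.40 ± 0.29 in Pre_only. IL13RA1 rose by 0.65 ± 0.10, whereas IL4R (0.10 ± 0.12, adjusted p = 0.635) and STAT6 (-0.11 ± 0.11, adjusted p = 0.556) were not called. SOCS1 rose by 1.23 ± 0.10, POSTN by 0.90 ± 0.21 and CCL26 by 0.80 ± 0.22, a call that ended without Pre_only P6-B. CCL11, undetected on all Control arrays, was not called (0.32 ± 0.31, adjusted p = 0.528). Among the falls, the chloride channel gene ANO1 was at least 6.91-fold lower and undetected on all Pre_only arrays. LCE2A changed by -3.49 ± 0.18, the small heat shock gene HSPB7 by -3.49 ± 0.15, KISS1 by -2.95 ± 0.20 and OXTR, the oxytocin receptor gene, by -2.77 ± 0.10. CORIN, MALL, SEMA7A, RAMP1 and RGS4 changed by -2.70 to -2.54.

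Of 19 IL-17 induced genes 15 rose and 0 fell (17 and 0 over the list alone; adjusted p = 5.49e-29, and 2.93e-04 with an estimated correlation). Of 28 TNF and NF-kB induced genes 18 rose and 1 fell, also over the list alone (adjusted p = 4.01e-17, and 4.87e-04 with an estimated correlation). SOD2, mitochondrial superoxide dismutase, rose by 4.13 ± 0.10 and CCL7 by 3.60 ± 0.21. Of 28 interferon response genes 20 rose and 1 fell (22 and 1 over the list alone; adjusted p = 1.64e-12, and 0.036 with an estimated correlation). These included IFI27 (2.27 ± 0.41), IFIT1 (2.01 ± 0.28) and MX1 (1.96 ± 0.21), and BST2, which was undetected on all Control arrays and at least 3.68-fold higher. In the class I antigen presentation list 14 of 16 rose, also over the list alone (adjusted p = 1.81e-15, and 0.00641 with an estimated correlation). PSMB9, an immunoproteasome subunit, rose by 1.87 ± 0.16, HLA-B by 1.57 ± 0.12, HLA-F by 1.54 ± 0.14 and the peptide transporter TAP2 by 1.22 ± 0.15.

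Of 27 cell cycle genes 19 rose and 1 fell (21 and 1 over the list alone; adjusted p = 4.75e-08, and 0.036 with an estimated correlation). CDC20 rose by 1.22, TOP2A, a DNA topoisomerase, by 1.17 and CCNB2, a mitotic cyclin, by 1.08, and AURKA, a mitotic kinase, fell by 1.70 ± 0.17. Smooth muscle markers fell in 7 of 10 cases, also over the list alone (adjusted p = 2.99e-08, and 0.00559 with an estimated correlation). The calponin gene CNN1 changed by -2.22 ± 0.19, the smooth muscle myosin gene MYH11 by -2.07 ± 0.16, NOTCH3 by -1.81 ± 0.14 and LMOD1 by -1.11 ± 0.12. Of 22 myofibroblast and TGF-beta genes 7 fell and 4 rose (10 and 4 over the list alone). LTBP2 changed by -1.54, the myosin light chain gene MYL9 by -1.19 and TGFB3 by -1.16, and the list had an adjusted p = 0.0163, and adjusted p = 0.189 with an estimated correlation. Cholesterol synthesis genes fell in 10 of 16 cases (13 over the list alone), among them MSMO1 (-0.97), HMGCS1 (-0.94), FDPS (-0.90) and MVD (-0.78). That list had an adjusted p = 1.82e-06, and 0.00801 with an estimated correlation.

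Of 23 matrix proteases and inhibitors 7 rose and 1 fell, also over the list alone (adjusted p = 7.38e-04, and 0.00709 with an estimated correlation). The stromelysin gene MMP3 rose by 4.01 ± 0.21 and ADAMTS5, an aggrecanase, by 1.88 ± 0.15. MMP12 and CTSS, cathepsin S, were at least 2.38-fold and 3.58-fold higher from undetected levels. In the oxidative stress and metallothionein list 8 of 20 rose (10 over the list alone), including the zinc transporter gene SLC39A8 (3.05 ± 0.19) and the metallothionein MT1F (2.91 ± 0.16). It had an adjusted p = 3.53e-05, and 0.0464 with an estimated correlation. Of 23 glycolysis and hypoxia genes 13 rose and 4 fell (14 and 4 over the list alone; adjusted p = 4.92e-04, and 0.0278 with an estimated correlation). CA12, a carbonic anhydrase (1.30), rose, and the glucose transporters SLC2A3 (-0.92) and SLC2A1 (-0.84) fell. Of 23 growth factors and survival cytokines 10 rose and 2 fell (12 and 2 over the list alone; adjusted p = 0.005, and 0.0417 with an estimated correlation). FGF2 changed by 1.77, GDF15 by 1.41, HGF by 1.30 and FGF1 by -1.06. Of the 13 IL-13 and IL-4 induced genes 7 rose and 2 fell, also over the list alone (adjusted p = 3.23e-04, and 0.0278 with an estimated correlation). DPP4 changed by 2.05 ± 0.12 and the transglutaminase TGM2 by -1.65 ± 0.18. Of 15 fibroblast markers 6 rose and 2 fell, also over the list alone, with TCF21 at 1.45 and COL3A1 at 1.42 (adjusted p = 0.0395, and adjusted p = 0.0501 with an estimated correlation).

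Several lists did not pass the test in this comparison although members were called. In the extracellular matrix list 7 rose and 9 fell of 31 (7 and 10 over the list alone; adjusted p = 0.503), with COL15A1 at -1.83 and fibronectin, FN1, at -1.15. In the prostaglandin pathway 5 rose and 3 fell of 15 (5 and 4 over the list alone; adjusted p = 0.171). PTGES rose by 3.53 ± 0.18, PTGS2, cyclooxygenase 2, by 3.34 ± 0.31 and AKR1C3 by 2.76 ± 0.38, and PTGIS fell by 1.44 ± 0.18. In the complement list 5 rose and 3 fell of 15 (adjusted p = 0.0597), with CFB, complement factor B, at 4.25 ± 0.11. The leukocyte list (2 rose of 9, adjusted p = 0.428) held CD14 (1.19) and CD68 (1.10), and its median was -0.10 where its mean was 0.16. Epithelial markers (1 fell of 4, adjusted p = 0.748), endothelial markers (1 rose and 1 fell of 2, adjusted p = 0.944), and the IL-13 receptor and STAT6 pathway (5 rose and 3 fell of 18, adjusted p = 0.102) did not pass either. Counts for these and for complement were the same over the list alone. The unfolded protein response (3 rose and 2 fell of 21, 3 and 3 over the list alone) had an adjusted p = 0.812.

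In total 3223 genes were called, of which 1559 rose and 1664 fell, and 534 changed at least 2-fold. The effect differed between the passages for 187 genes, IL13RA2 (4.32 in passage 6, 3.21 in passage 8) and 12 of the 28 interferon response genes among them. With passage 6 alone 2463 genes were called, and with passage 8 alone, where Pre_only has 1 array, 1774. With median scaling 1945 were called, 742 of which rose and 1203 fell, and adjusted over all comparisons together 2127.

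**Figure D3:**
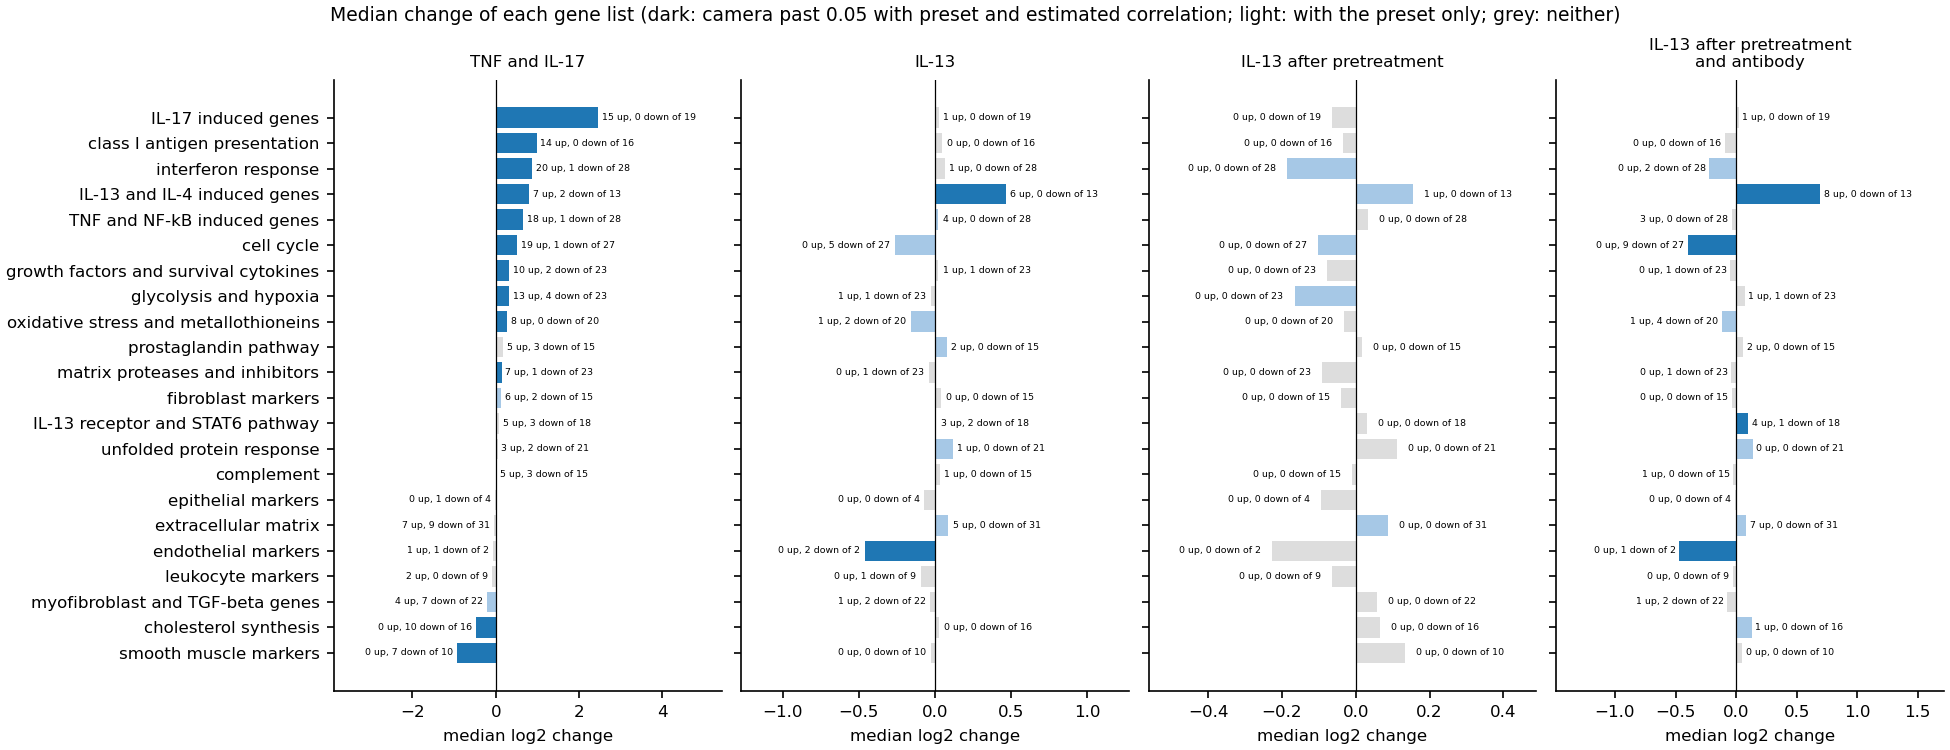
Median log2 change of the tested members of each of 22 gene lists in 4 comparisons, each on its own axis, with the number of called members beside each bar; dark bars passed camera with both the preset and the estimated correlation, light bars with the preset one alone, grey bars with neither. IL-17 induced genes have a median of 2.46 with pretreatment, and IL-13 and IL-4 induced genes one of 0.46 with IL-13, 0.16 with IL-13 after pretreatment and 0.70 after pretreatment and antibody.

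The response of pretreated cells to IL-13 was taken from Pre_IL13 against Pre_only. CCL26 rose by 2.55 ± 0.22 (n = 4 and 3, adjusted p = 1.25e-08), by 1.92 in passage 6 and 3.26 in passage 8. The other 3 called genes were CDH6, a cadherin (0.80 ± 0.14), WFDC1 (0.67 ± 0.12) and OXTR (0.52 ± 0.10), each with an adjusted p = 0.0268, and 0 genes fell. CCL11 (0.89 ± 0.31, adjusted p = 0.537), POSTN (0.35 ± 0.21, adjusted p = 0.823), SOCS1 (0.16 ± 0.10, adjusted p = 0.83) and IL13RA2 (0.27 ± 0.15, adjusted p = 0.813) were not called. Nor were IL13RA1 (-0.32 ± 0.10, adjusted p = 0.462), IL4R (0.20 ± 0.12, adjusted p = 0.823) and STAT6 (-0.11 ± 0.11, adjusted p = 0.886). Of the 13 IL-13 and IL-4 induced genes 1 rose (2 over the list alone; adjusted p = 8.92e-04, and adjusted p = 0.0976 with an estimated correlation). A further 4 lists passed with the preset correlation, in each of which limma called 0 members over all genes. The cell cycle list had a median of -0.10 (0 over the list alone; adjusted p = 8.92e-04, and adjusted p = 0.385 with an estimated correlation). The glycolysis and hypoxia list had a median of -0.17 (2 falls over the list alone; adjusted p = 2.84e-04, and adjusted p = 0.0729 with an estimated correlation). The interferon response list had a median of -0.19 (0 over the list alone; adjusted p = 0.00119, and adjusted p = 0.472 with an estimated correlation). The extracellular matrix list had a median of 0.09 (2 rises over the list alone; adjusted p = 0.00748, and adjusted p = 0.5 with an estimated correlation).

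Of the 12994 genes, 833 had an unadjusted p under 0.05, where chance gives 650. Single arrays decided this count: 45 genes were called without Pre_only P8-B, 1 without Pre_only P6-A, Pre_only P6-B or Pre_IL13 P8-A, and 2 without any of the other Pre_IL13 arrays. The calls of CDH6, WFDC1 and OXTR each ended without some of them, and 28 genes were called with passage 6 alone. Blocking by passage and experiment, leaving out the passage term or averaging A and B left 1 call, and median scaling or a random block of group and passage 2, whereas adjustment over all comparisons together gave 49.

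The difference between these responses was tested directly, as (Pre_IL13 minus Pre_only) minus (IL13 minus Control), to ask whether pretreatment changed the response to IL-13. The change was -2.67 ± 0.42 for CCL11 (adjusted p = 7.19e-04), which was undetected on all Control arrays, with -3.97 in passage 6 and -1.45 in passage 8. It was -2.47 ± 0.29 for CCL26 (adjusted p = 1.45e-05), -1.63 ± 0.24 for ST8SIA1 (undetected on all Pre_only arrays), -1.53 ± 0.28 for CCL7 and -1.49 ± 0.24 for LRRC8B. Changes of lesser size were -1.40 ± 0.16 for C1QTNF1, -1.22 ± 0.24 for PTGIS, -0.998 ± 0.14 for SOCS1, -0.92 ± 0.14 for CCL2 and -0.64 ± 0.13 for VCAM1. For TRIM55 (1.03 ± 0.19), ADAMTS1 (0.93 ± 0.14), MARCHF4 (0.93 ± 0.19), CLDN1 (0.87 ± 0.17) and DRAM1 (0.72 ± 0.16) the change was positive. TRIM55, ADAMTS1, CLDN1 and DRAM1 had fallen with IL-13 in cells without pretreatment. IL13RA2 (-0.76 ± 0.21, adjusted p = 0.191), POSTN (-0.86 ± 0.29, adjusted p = 0.347), IL13RA1 (-0.22 ± 0.14, adjusted p = 0.719), IL4R (0.04 ± 0.16, adjusted p = 0.973) and STAT6 (0.07 ± 0.15, adjusted p = 0.944) were not called. Of the 13 IL-13 and IL-4 induced genes, 3 had a smaller response (6 over the list alone; adjusted p = 5.73e-10, and 0.00226 with an estimated correlation). The TNF and NF-kB list was negative as well (3 smaller of 28, 4 over the list alone; adjusted p = 0.0353, and adjusted p = 0.319 with an estimated correlation). So were the interferon response list (0 of 28, 1 over the list alone; adjusted p = 0.0013, and adjusted p = 0.432 with an estimated correlation) and the glycolysis and hypoxia list (0 of 23, 0 over the list alone; adjusted p = 0.0148, and adjusted p = 0.222 with an estimated correlation).

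In total 39 genes had a changed response, 33 negative and 6 positive, and 20 of them by at least 2-fold. The 33 genes with a negative change had all risen with IL-13 without pretreatment, a response that is part of this difference, with a median of 1.06 against 0.09 after it, and 13 of the 33 had been raised by pretreatment alone. The count was 25 without Control P6-B, 21 without Pre_only P6-B, 68 without Pre_only P8-B, 114 with passage 6 alone and 8 with passage 8 alone, where Pre_only has 1 array. It was 9 with median scaling, 3 with the mean of A and B, 22 with the passage term left out and 86 adjusted over all comparisons together. Leaving out 1 array ended the calls of MARCHF4, DRAM1, VCAM1 and PTGIS.

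Cells given the antibody after pretreatment served for the same question with IL-13Ra2 blocked. In Pre_Ab_IL13 against Pre_Ab_only, CCL26 rose by 4.77 ± 0.20 (n = 4 and 4, adjusted p = 7.08e-17), CCL11 by 2.62 ± 0.28, ST8SIA1 by 2.27 ± 0.16 and BATF3 by 2.17 ± 0.19. NPPB, natriuretic peptide B, rose by 2.03 ± 0.34, ANPEP by 1.99 ± 0.16 and SPINT2, a protease inhibitor, by 1.65 ± 0.19. For NPPB the effect of IL-13 without pretreatment differed between the passages, with 0.06 in passage 8. In that passage NPPB rose by 1.21 with IL-13 after pretreatment without antibody (1 Pre_only array). GRB14, a receptor adaptor, changed by -1.38 ± 0.11, the death ligand gene TNFSF10 by -1.37 ± 0.27 and PDK4, a pyruvate dehydrogenase kinase, by -1.28 ± 0.26. FMO2 (-1.14 ± 0.31), NR4A2 (-1.13 ± 0.22), AKR1B10 (-1.11 ± 0.21), UBE2C (-1.07 ± 0.14) and NPTX1 (-1.05 ± 0.18) fell too. IL4R rose by 0.56 ± 0.11 (adjusted p = 0.00221), IL13RA2 by 0.70 ± 0.14 and SOCS1 by 0.80 ± 0.10. IL13RA1 (-0.09 ± 0.10, adjusted p = 0.841) and STAT6 (-0.13 ± 0.10, adjusted p = 0.757) were not called.

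Of the 13 IL-13 and IL-4 induced genes 8 rose and 0 fell (8 and 1 over the list alone; adjusted p = 1.44e-16, and 1.43e-04 with an estimated correlation). TGM2 rose by 1.13 ± 0.17 and POSTN by 0.72 ± 0.20, and CISH was at least 1.44-fold higher from undetected levels. In the IL-13 receptor and STAT6 pathway 4 of 18 rose and 1, SOCS2 (-0.58), fell (4 and 2 over the list alone; adjusted p = 0.0135, and 0.0463 with an estimated correlation). Of 27 cell cycle genes 9 fell (18 over the list alone; adjusted p = 6.3e-23, and 0.00206 with an estimated correlation). UBE2C, TOP2A (-0.88), CENPF (-0.81) and CDC20 (-0.80) were among them. In the extracellular matrix list 7 of 31 rose (12 over the list alone, with 1 fall), including TNC (0.89), COL6A1 (0.72) and COL6A2 (0.70). This gave an adjusted p = 3.8e-05, and adjusted p = 0.214 with an estimated correlation. In the oxidative stress and metallothionein list of 20, MT1M (-0.90), MT1X (-0.66), HMOX1, heme oxygenase 1 (-0.62), and MT1G (-0.60) fell and 1 gene rose. Over the list alone 7 fell and 2 rose (adjusted p = 1.67e-04, and adjusted p = 0.115 with an estimated correlation). IFI44L (-0.74) and TRIM22 (-0.48) were the 2 of 28 interferon response genes that fell (4 over the list alone, with 1 rise; adjusted p = 5.42e-04, and adjusted p = 0.316 with an estimated correlation). INSIG1 (0.68) was the 1 of 16 cholesterol synthesis genes that rose (2 over the list alone; adjusted p = 0.00215, and adjusted p = 0.115 with an estimated correlation). The unfolded protein response list (0 of 21, 4 rises over the list alone; adjusted p = 1.82e-04, and adjusted p = 0.214 with an estimated correlation) passed too. Of the pair of endothelial markers TEK (-0.53) fell (2 over the list alone; adjusted p = 4.04e-04, and 0.0137 with an estimated correlation).

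In total 291 genes were called, of which 150 rose and 141 fell. Of the 150 genes that rose with IL-13 without pretreatment, 75 also rose here, where chance gives 1.73. Of the 93 that fell, 32 also fell, where chance gives 1.01, and no array is shared between these comparisons. The count was 123 with passage 6 alone and 325 with passage 8 alone, 149 with the passage term left out, 161 with median scaling, 75 with the mean of A and B and 596 with only the groups compared in the fit. Leaving out 1 array ended the calls of FMO2, POSTN, SOCS2, HMOX1, MT1G, IFI44L and TRIM22.

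**Figure D4:**
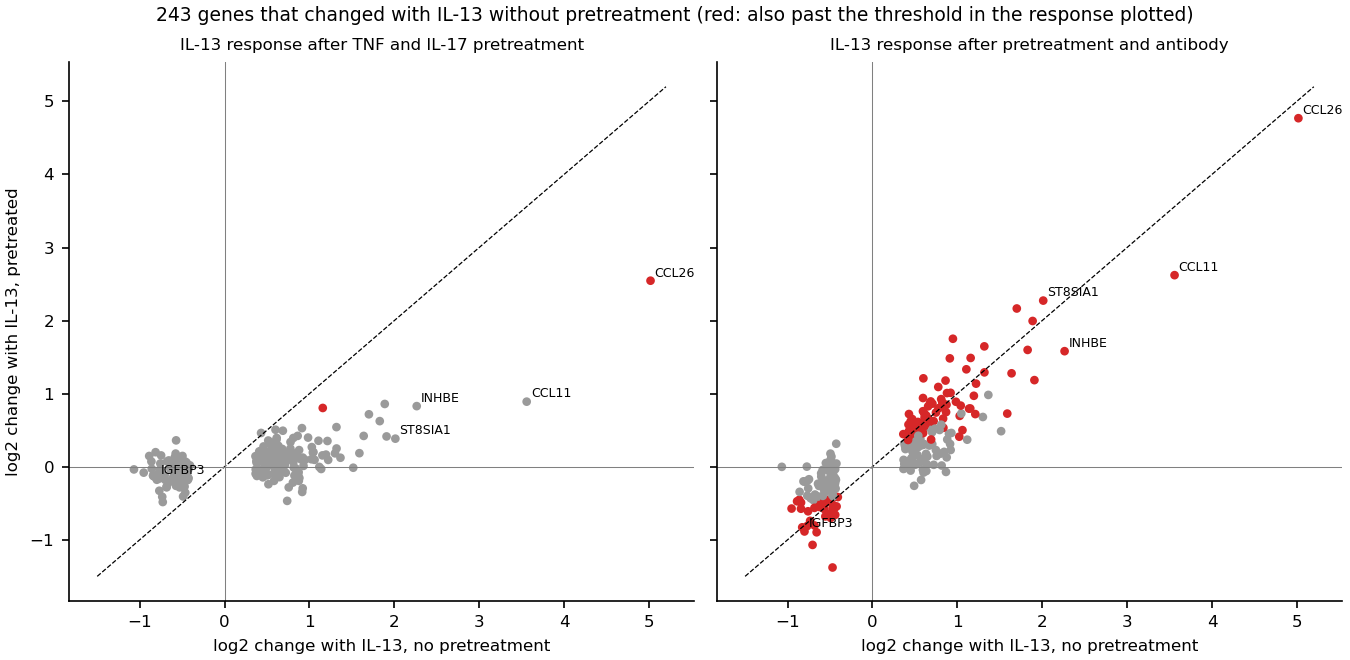
Log2 change with IL-13 after pretreatment (left) and after pretreatment and antibody (right) against that without pretreatment, for the 243 genes called in the latter; red points were also called in the response on the vertical axis, and the dashed line marks equal change. On the left 2 genes are red, and on the right 75 that rose and 32 that fell are.

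The antibody was compared without IL-13, Pre_Ab_only against Pre_only, and limma called 0 genes. The lowest adjusted p was 0.497, and 659 genes had an unadjusted p under 0.05, where chance gives 650. CCL26 (0.02 ± 0.22), CCL11 (0.06 ± 0.31), SOCS1 (0.01 ± 0.10), POSTN (0.19 ± 0.21), IL13RA2 (-0.18 ± 0.15), IL13RA1 (-0.10 ± 0.10), IL4R (0.02 ± 0.12) and STAT6 (-0.05 ± 0.11) had adjusted p of 0.977 or more. Without Pre_only P8-B 2 genes were called, and 14 adjusted over all comparisons together. The many genes changed by pretreatment ease the threshold of that wider adjustment, so it does not bound the share of false calls among these 14. The same 3 Pre_only arrays enter this comparison, IL-13 after pretreatment and the changes by pretreatment and antibody, so their list results are not independent. A high level of the glycolysis and hypoxia list in Pre_only alone would give the signs of its shifts in each of them. The glycolysis and hypoxia list was lower with the antibody (median -0.13, 0 of 23 called, 1 over the list alone; adjusted p = 6.16e-06, and 0.02 with an estimated correlation). The TNF and NF-kB list was lower too (median -0.14, 0 of 28, 1 over the list alone; adjusted p = 5.69e-05, and adjusted p = 0.113 with an estimated correlation). For the IL-17 list the median was -0.20 (0 of 19, 0 over the list alone; adjusted p = 0.0289, and adjusted p = 0.566 with an estimated correlation).

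With IL-13 present, Pre_Ab_IL13 against Pre_IL13 differed in 120 genes. CCL26 was higher by 2.25 ± 0.20 (n = 4 and 4, adjusted p = 2.49e-08), ST8SIA1 by 1.81 ± 0.16 and CCL11 by 1.79 ± 0.28. BATF3 was higher by 1.32 ± 0.19, SIPA1L2 by 1.25 ± 0.13, PTGIS by 1.19 ± 0.16 and NFIL3, a transcription factor, by 1.18 ± 0.12. GRB14 changed by -1.14 ± 0.11, NR4A2 by -1.01 ± 0.22, FAM43A by -0.97 ± 0.17 and NPTX1 by -0.95 ± 0.18. CLDN1 (-0.88 ± 0.11), RASGRP3 (-0.83 ± 0.14), TOP2A (-0.81 ± 0.14) and VWA5A (-0.78 ± 0.13) were lower as well. SOCS1 was higher by 0.65 ± 0.10. IL13RA2 (0.25 ± 0.14, adjusted p = 0.69), IL13RA1 (0.13 ± 0.10, adjusted p = 0.817), IL4R (0.38 ± 0.11, adjusted p = 0.106), STAT6 (-0.06 ± 0.10, adjusted p = 0.954) and POSTN (0.56 ± 0.20, adjusted p = 0.308) were not called. Of the 13 IL-13 and IL-4 induced genes 4 were higher (7 over the list alone; adjusted p = 1.64e-11, and 0.00121 with an estimated correlation), with CISH at least 1.45-fold higher from undetected levels. Of 27 cell cycle genes 5 were lower (15 over the list alone; adjusted p = 4.82e-17, and 0.00831 with an estimated correlation), UBE2C (-0.70) and TOP2A among them. In the extracellular matrix list TNC (0.64) and COL6A1 (0.46) were higher (2 of 31, 4 over the list alone; adjusted p = 5.24e-04, and adjusted p = 0.276 with an estimated correlation). In the IL-13 receptor and STAT6 pathway 2 were higher and SOCS2 (-0.66) was lower (3 and 2 over the list alone; adjusted p = 0.0382, and adjusted p = 0.124 with an estimated correlation). INSIG1 (0.42) was the 1 of 16 cholesterol synthesis genes that was higher, on either adjustment (adjusted p = 0.0124, and adjusted p = 0.223 with an estimated correlation). The unfolded protein response list was higher (0 of 21 on either adjustment; adjusted p = 0.0262, and adjusted p = 0.442 with an estimated correlation). The TNF and NF-kB list was lower (adjusted p = 0.0262, and adjusted p = 0.274 with an estimated correlation) although its 1 called member, TRAF1 (1.02 ± 0.13), was higher, also over the list alone. The interferon response list was lower (0 of 28 on either adjustment; adjusted p = 0.0382, and adjusted p = 0.464 with an estimated correlation). So was the class I list (0 of 16 on either adjustment; adjusted p = 0.0497, and adjusted p = 0.442 with an estimated correlation). Of the 120 genes 88 were higher and 32 lower. Leaving out 1 array ended the calls of NR4A2, UBE2C, TNC and INSIG1. The count was 73 without Pre_IL13 P6-A, 78 with passage 6 alone and 212 with passage 8 alone, 62 with the passage term left out, 61 with median scaling, 25 with the mean of A and B and 261 with only the groups compared in the fit.

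The change of the pretreated response by the antibody, (Pre_Ab_IL13 minus Pre_Ab_only) minus (Pre_IL13 minus Pre_only), was 2.22 ± 0.29 for CCL26 (adjusted p = 8.54e-05). It was 1.89 ± 0.24 for ST8SIA1 (undetected on all Pre_only arrays), 1.45 ± 0.28 for BATF3 and 1.43 ± 0.17 for STEAP1. It was -1.31 ± 0.27 for NPTX1, -1.19 ± 0.17 for GRB14, -0.95 ± 0.21 for UBE2C and -0.69 ± 0.15 for SLC38A4-AS1. CCL11 (1.73 ± 0.42, adjusted p = 0.0958) was not called, though it was without any of 3 IL13 arrays (P6-B, P8-A or P8-B). Also not called were IL13RA2 (0.43 ± 0.21, adjusted p = 0.751), IL13RA1 (0.23 ± 0.14, adjusted p = 0.836), IL4R (0.36 ± 0.16, adjusted p = 0.705), STAT6 (-0.02 ± 0.15, adjusted p = 0.992) and POSTN (0.37 ± 0.29, adjusted p = 0.896). Of the 13 IL-13 and IL-4 induced genes 3 had a larger response, SOCS1 (0.64 ± 0.14) and CISH besides CCL26. CISH (0.89 ± 0.19) was detected in Pre_Ab_IL13 alone of the 4 groups compared, so the size of its difference is not known. Over the list alone 5 were larger and 1 smaller (adjusted p = 7.71e-09, and 0.00432 with an estimated correlation). The glycolysis and hypoxia list was positive (median 0.21, 0 of 23 called, 3 over the list alone; adjusted p = 3.29e-06, and 0.0116 with an estimated correlation). The cell cycle list was negative (1 of 27, 3 over the list alone; adjusted p = 7.71e-09, and adjusted p = 0.0549 with an estimated correlation). The oxidative stress and metallothionein list was negative too (0 of 20, 5 negative and 1 positive over the list alone; adjusted p = 0.0393, and adjusted p = 0.437 with an estimated correlation). The IL-13 receptor and STAT6 pathway was positive (2 of 18, 2 and 1 over the list alone; adjusted p = 0.038, and adjusted p = 0.0549 with an estimated correlation). The glycolysis and hypoxia list was not among those that passed for the antibody with IL-13. Because Pre_only enters this difference, a high level of that list in Pre_only alone would make its difference positive. In total 30 genes were called, 26 positive and 4 negative. The count was 18 without Pre_IL13 P6-A or without Pre_only P6-A, 31 with passage 6 alone, 18 with passage 8 alone (1 Pre_only array), 16 with the passage term left out and 61 with only the groups compared in the fit. It was 11 with median scaling, 3 with the mean of A and B and 73 adjusted over all comparisons together. Leaving out any of several single arrays ended the calls of BATF3, NPTX1, UBE2C, SLC38A4-AS1, CISH and SOCS1.

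Set against the response without pretreatment, the response after pretreatment and antibody differed in 9 genes, with 6 positive and 3 negative differences. STEAP1 (1.69 ± 0.16, adjusted p = 2.34e-07), SIPA1L2 (1.12 ± 0.18) and LXN, latexin (1.00 ± 0.18), had the larger response after pretreatment and antibody. So did the hyaluronan synthase gene HAS3 (1.23 ± 0.22), undetected on all Control, IL13 and Pre_Ab_only arrays, so the size of its difference is not known. The response was also larger for IL1RL1, the receptor of IL-33 (0.85 ± 0.17), undetected on all Pre_Ab_only arrays. OXTR (0.67) was the other gene with a larger response, chosen after its values were seen. STEAP1 had a level of 7.57 in Control, 7.23 in IL13, 8.55 in Pre_Ab_only and 9.90 in Pre_Ab_IL13. SOX11 (-0.94 ± 0.14), GRB14 (-0.91 ± 0.16) and C1QTNF1 (-0.86 ± 0.15) were the 3 genes with a negative difference. GRB14 had -0.47 with IL-13 without pretreatment and -1.38 after pretreatment and antibody. Its level was 5.09 in Control, 4.62 in IL13 (detected on 2 arrays) and 7.06 in Pre_Ab_only. A detection floor that limits its fall without pretreatment stays open. SOX11 was detected on 1 Control, 4 IL13, 2 Pre_Ab_only and 1 Pre_Ab_IL13 arrays. CCL11 (-0.94 ± 0.40, adjusted p = 0.779), again undetected in Control, was not called, but its difference was -2.02 in passage 6 and 0.14 in passage 8, and the passages differed for it. CCL26 (-0.25 ± 0.28, adjusted p = 0.967), SOCS1 (-0.36 ± 0.14, adjusted p = 0.71) and POSTN (-0.49 ± 0.28, adjusted p = 0.871) were not called. Neither were IL13RA2 (-0.33 ± 0.20, adjusted p = 0.876), IL13RA1 (0.01 ± 0.14, adjusted p = 0.998), IL4R (0.40 ± 0.15, adjusted p = 0.71) and STAT6 (0.06 ± 0.14, adjusted p = 0.989). The interferon response list was negative (0 of 28 on either adjustment; adjusted p = 2.02e-05, and adjusted p = 0.579 with an estimated correlation). The cell cycle list (0 of 27, 1 over the list alone; adjusted p = 0.00106, and adjusted p = 0.579 with an estimated correlation) and the class I list (0 of 16 on either adjustment; adjusted p = 0.0275, and adjusted p = 0.579 with an estimated correlation) were negative as well. The count was 14 without Pre_Ab_only P6-A or without IL13 P8-A, 22 with passage 6 alone, 24 with passage 8 alone and 23 with the authors' values or without background correction. It was 1 with the mean of A and B and 50 adjusted over all comparisons together. The call of IL1RL1 ended without any 1 of 16 arrays.

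Genes chosen for their rise with IL-13 in 1 passage were measured in the other, so that choice and measurement shared no arrays. The 124 genes chosen in passage 6 had a median change in passage 8 of 0.53 without pretreatment, 0.14 after pretreatment (1 Pre_only array) and 0.49 after pretreatment and antibody. Of these, 108 responded less after pretreatment and 105 responded more with the antibody. The 76 genes chosen in passage 8 had medians in passage 6 of 0.91, 0.13 and 0.72, with 71 and 66 such genes. The means of both passages' medians were 0.72, 0.13 and 0.60, and became 0.93, 0.37 and 0.94 with median scaling and 1.15, 0.28 and 1.01 with a selection at 2-fold. Pretreatment alone moved these sets by a median of 0.05 and -0.16. For the 105 genes chosen for their fall in passage 6 the medians were -0.20, -0.03 and -0.17, and for the 37 chosen in passage 8 they were -0.37, -0.03 and -0.45. For the genes that fell, the mean of both passages' medians after pretreatment was -0.03 and changed sign without background correction (0.01) and with median scaling (0.15).

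**Figure D5:**
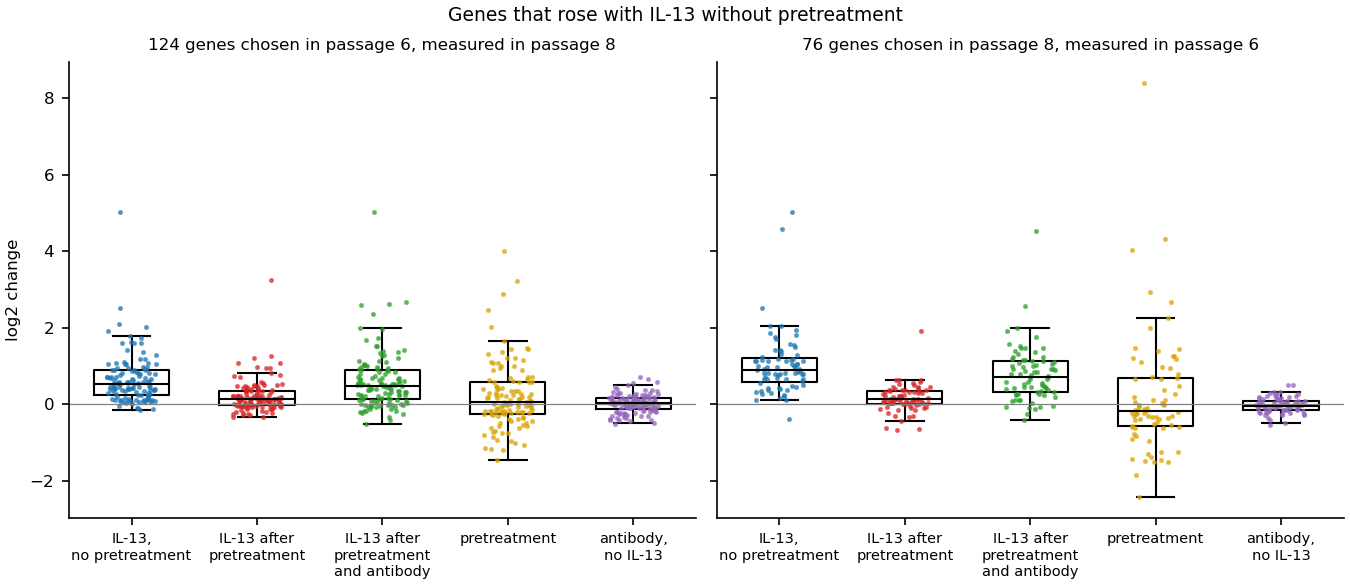
Log2 changes in 1 passage of genes chosen for their rise with IL-13 without pretreatment in the other passage, in 5 comparisons; points are genes, boxes give median and quartiles and whiskers reach at most 1.5 times the box. For the 124 genes on the left the medians with IL-13 are 0.53, 0.14 and 0.49 without pretreatment, after it, and after it with antibody, and for the 76 genes on the right they are 0.91, 0.13 and 0.72.

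The score of the 13 IL-13 and IL-4 induced genes was 6.25 ± 0.05 (SD, n = 4) in Control, 7.28 ± 0.14 (n = 4) in IL13, 6.94 ± 0.07 (n = 3) in Pre_only, 7.29 ± 0.16 (n = 4) in Pre_IL13, 6.92 ± 0.08 (n = 4) in Pre_Ab_only and 7.84 ± 0.07 (n = 4) in Pre_Ab_IL13. Two-sided exact permutation tests gave p = 0.0286, the smallest these group sizes allow, for IL-13 without pretreatment (1.03), for pretreatment (0.70), for IL-13 after pretreatment and antibody (0.92) and for the antibody with IL-13 (0.55), each with an adjusted p = 0.0429. For IL-13 after pretreatment the difference was 0.35 (exact p = 0.0571, adjusted p = 0.0686), and for the antibody without IL-13 it was -0.02 (exact p = 0.743). Within passage 6 and passage 8 the differences were 1.16 and 0.90 for IL-13 without pretreatment, 0.25 and 0.41 after pretreatment and 0.93 and 0.91 after pretreatment and antibody. The score is a plain mean, so members with large changes weigh most in it. With IL-13 without pretreatment these were CCL26 (5.02) and CCL11 (3.56), and after pretreatment CCL26 (2.55). With pretreatment itself IL13RA2 and DPP4 rose most.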

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

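The counts of other splits and the tests of array quality, IL13RA2, the beadchips, the detection floor and the antibody on its own were chosen after the results were seen, as was the raised baseline over genes that pretreatment did not raise.

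The response to IL-13 was smaller after pretreatment, changed in 39 genes, and still in 28 without both IL13 arrays of passage 6, which argues against lower quality of those arrays as the whole cause. A raised baseline that leaves no room to rise cannot act in the genes that pretreatment did not raise. Their median response measured in the other passage was at most 0.25 of that without pretreatment (0.2498). This argues against a raised baseline as the whole cause, and does not judge it in genes where it could act. In the 13 genes that pretreatment raised, the median ratio of the response with antibody to that without pretreatment was 0.539, between the bounds of 0.3 and 0.8 set for it, so a raised baseline there stays open. IL-13 held back by IL13RA2, which rose with pretreatment and which the antibody blocks, is a candidate explanation: the lower of the 2 median gains by antibody measured in the other passage was 0.32, against 0.03 and -0.04 for the antibody alone in the gene sets chosen in passage 6 and passage 8. No group had the antibody without pretreatment or a control antibody, so other effects of TNF and IL-17 remain open.

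The effect of pretreatment differed between the passages for 187 genes. A uniform compression of log2 changes on 1 beadchip would need all of them smaller in the same passage: 80.8% were smaller in passage 8, between the bounds of 95 and 80 set for it, but 36 were larger there and 55 had opposite signs, which argues against it, a point looked at afterwards. The single Pre_only array of passage 8 is argued against as the whole cause, since 73.8% of the genes had a called difference of the same sign with Pre_Ab_only in its place. Passage and beadchip cannot be told apart, because each passage had its own beadchip, and 3820 genes differed between them. Biological change with passage may therefore contribute, and it was not tested separately.

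The response after pretreatment and antibody was larger than that without pretreatment in 6 genes. A detection floor that hides the response without pretreatment is argued against for the 3 of 6 genes detected on all Control and IL13 arrays. For the other genes it stays open: 2 of those 3 were detected on at least as many Control as Pre_Ab_only arrays. The antibody acting without IL-13 cannot be judged by the ratio of its median change to that with IL-13 (-0.0457), since these genes were chosen by a difference that subtracts Pre_Ab_only. No biological explanation was tested, and a joint effect of pretreatment and IL-13 may remain as a hypothesis.

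Other splits of the same arrays were counted for each comparison, and each total includes the real grouping. For IL-13 without pretreatment 2 of 35 splits called as many genes as the real 243, so chance is not excluded by this count. The other, with 778 genes, parts the arrays of passage 6 from those of passage 8, which points to a structure of the samples; passage is a term of the model, and 234 and 146 genes were called within passage 6 and passage 8. Only the real grouping of the 35 splits called as many genes for pretreatment (3223 genes, highest other 1787). The same held for IL-13 after pretreatment and antibody (291, highest other 5) and the antibody with IL-13 (120, highest other 6). A share of 1 of 35 is the smallest these splits allow and was not adjusted over the comparisons. It argues against chance for these comparisons and does not exclude it. For the 4 genes of IL-13 after pretreatment the share was also 1 of 35 splits. Chance is not firmly excluded there, because that count rests on single arrays. It is 1, as many as in the highest other split, without Pre_only P6-A, Pre_only P6-B or Pre_IL13 P8-A and with the replicate block. For the antibody without IL-13 limma called 0 genes, which any split must reach, so this count cannot judge that comparison. In it 659 genes had an unadjusted p under 0.05, and the highest other split called 50. For differences between responses, residuals were permuted, again with the real grouping among the 100: 3 gave as many as 39 genes for the change by pretreatment, 2 of them permuted, with up to 94. For the change by antibody only the real grouping gave 30, with 23 as the highest other. For the response after antibody against that without pretreatment it was 3 of 100 for 9 genes, 2 of them permuted, with up to 87. For the change by antibody the share was 1 of 100, the smallest these draws allow. Its count was 18 without Pre_IL13 P6-A or without Pre_only P6-A, under the 23 of the highest other draw. Chance is therefore not firmly excluded for the change by antibody. For the other differences the share was 3 of 100, but permuted draws with 94 and 87 genes passed the real counts. Chance is therefore not firmly excluded for them, and these draws point to a structure of the residuals.

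Changes of the IL-13 response by pretreatment were 1.03 for TRIM55, 0.93 for ADAMTS1, 0.93 for MARCHF4, 0.87 for CLDN1 and 0.72 for DRAM1. They were -2.67 for CCL11, -2.47 for CCL26, -1.63 for ST8SIA1, -1.53 for CCL7, -1.49 for LRRC8B, -1.40 for C1QTNF1, -1.22 for PTGIS, -1 for SOCS1, -0.92 for CCL2 and -0.64 for VCAM1. Changes by antibody, called in 30 genes, were 2.22 for CCL26, 1.89 for ST8SIA1, 1.45 for BATF3, 1.43 for STEAP1, 0.89 for CISH (detected in 1 of the 4 groups compared), 0.64 for SOCS1, -1.31 for NPTX1, -1.19 for GRB14, -0.95 for UBE2C and -0.69 for SLC38A4-AS1. Against the response without pretreatment, 9 genes differed, with 1.69 for STEAP1, 1.23 for HAS3, 1.12 for SIPA1L2, 1 for LXN, 0.85 for IL1RL1, -0.94 for SOX11, -0.91 for GRB14 and -0.86 for C1QTNF1. Values for CCL11, ST8SIA1, HAS3 and IL1RL1 also rest on groups without detection: Control for CCL11, Pre_only for ST8SIA1, Pre_Ab_only for IL1RL1, and Control, IL13 and Pre_Ab_only for HAS3. SOX11 and GRB14 lacked detection on some arrays of the groups compared.

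Effects differed between the passages in 3 genes for IL-13 without pretreatment, 22 for IL-13 after pretreatment, 10 after pretreatment and antibody, 15 for the change by pretreatment and 3 for the response after antibody against that without pretreatment. Passage 8 minus passage 6, the effect of IL-13 differed by -2.06 for CCL11 without pretreatment, by 1.34 for CCL26 after pretreatment, and by 1.18 for ANPEP, 1.29 for TNFSF10 and 1.71 for PDK4 after pretreatment and antibody, and the change by pretreatment differed by 2.51 for CCL11. The effect of pretreatment differed by 1.45 for CXCL8, -1.27 for KYNU, 0.95 for COXFA4L3, 1.13 for RAMP1, -1.11 for IL13RA2, 0.84 for TGM2, -1.15 for CCL7, 1.21 for CNN1, 1 for MYL9, 1.69 for TGFB3 and 0.86 for MMP3. It differed by -2.58 for IFI27, -2.3 for IFIT1, -1.56 for MX1, -1.42 for BST2, 1.16 for AURKA, -1.11 for CA12, 0.99 for SLC2A1, -1.14 for PTGES, -2.91 for AKR1C3 and 0.99 for MYH11.

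A single array stood apart from its group, with a gap to the nearest other over the whole range above Dixon's critical value for 4 arrays, in 34 of 820 groups of the named genes (4.15%), and chance gives about 5 in 100. The 5 in 100 holds for arrays that are alike, whereas each group mixes 2 passages. The ratio also ignores the size of a gap: IL6 in Pre_Ab_only had 12.278 on P8-B against a mean of 12.257 on the others. Detected probes in Pre_IL13 had a ratio of 0.8294, only just above the critical value, where P6-A had 18758. Gene ratios in Pre_IL13 were 0.889 for IL13RA2, 0.956 for POSTN, 0.88 for PTGIS, 0.841 for KISS1, 0.903 for LOX, 0.857 for VWF, 0.921 for CORIN, 0.871 for COL3A1, 0.836 for HMOX1, 0.965 for CD68, 0.94 for TGFBR2 and 0.917 for SLC38A4-AS1. In IL13 they were 0.889 for VWF, 0.869 for CD14, 0.839 for ANO1, 0.891 for MALL, 0.93 for SEMA7A, 0.925 for SLC2A3, 0.88 for MSMO1, 0.923 for FDPS, 0.834 for GDF15 and 0.838 for NFIL3. In Pre_Ab_IL13 they were 0.839 for KISS1, 0.853 for SMAD3, 0.871 for UBE2C, 0.899 for ANO1 and 0.861 for SLC38A4-AS1. In Pre_Ab_only they were 0.885 for IL6, 0.853 for CXCL5, 0.832 for ANO1 and 0.978 for HGF, and in Control 0.841 for CXCL5, 0.925 for SOCS2 and 0.922 for MT1E.

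Probes without a single gene name and with a value on every array, 6555 in number, were tested apart: 28 were called for IL-13 without pretreatment, 484 for pretreatment, 26 for IL-13 after pretreatment and antibody and 10 for the antibody with IL-13.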

How the results depend on the processing

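Leaving out both IL13 arrays of passage 6 was chosen after the results were seen. No called named gene changed sign in any alternative, and the cause of the differences below was not tested except where fewer arrays, a larger minimum change or a wider adjustment is the alternative itself. Counts of called genes are given in the order of the text where they moved by over 1.5 times. With median scaling they were 92 for IL-13, 1945 for pretreatment, 2 for IL-13 after pretreatment, 161 for IL-13 after pretreatment and antibody, 61 for the antibody with IL-13, 9 for the change by pretreatment and 11 for the change by antibody. Under that scaling the median of all genes was -0.12 for IL-13, 0.14 for IL-13 after pretreatment, 0.20 for the antibody alone, 0.26 for the change by pretreatment and -0.19 for the change by antibody, and 742 of the 1945 genes called for pretreatment then rose, against 1559 of 3223. With the passage term left out the counts were 113, 1 (IL-13 after pretreatment), 149 (with antibody), 62 (antibody with IL-13), 22 and 16 (changes by pretreatment and antibody). With the mean of A and B they were 55, 1, 75, 25, 3, 3 and 1 for all but pretreatment and the antibody alone. With passage 6 only they were 28 (IL-13 after pretreatment), 123 (with antibody), 78 (antibody with IL-13), 114 (change by pretreatment) and 22 (response after antibody against that without pretreatment). With passage 8 only, where Pre_only has 1 array, they were 146 (IL-13), 1774 (pretreatment), 1 (antibody alone), 212 (antibody with IL-13), 8 and 18 (changes by pretreatment and antibody) and 24 (response after antibody against that without pretreatment). At least 2-fold changes numbered 29, 534, 1, 42, 18, 20, 19 and 3 for all but the antibody alone. Adjustment over all comparisons together pools their p-values, so the many changes with pretreatment ease the threshold for the other comparisons. With it the counts were 2127 (pretreatment), 49 (IL-13 after pretreatment), 14 (antibody alone), 86, 73 and 50 (the differences between responses). With only the groups compared they were 596, 261 and 61 (IL-13 after pretreatment and antibody, antibody with IL-13, change by antibody), and with array weights 622, 255, 47 and 16 (the same and the response after antibody against that without pretreatment), the lowest weight being 0.248 for IL13 P6-A. That last count was 23 without background correction and 23 with the authors' values. With the replicate block of passage and experiment the counts were 221, 3074, 1, 273, 0, 106, 32, 24 and 8 over the 9 comparisons, and a random block of group and passage gave 2 for IL-13 after pretreatment. Pairing of arrays by the experiment letters was not seen but is not ruled out: the median correlation of residuals was -0.12 with the same letter (highest 0.398) and -0.09 with the other (highest 0.23). Without both IL13 arrays of passage 6 the counts were 97 (IL-13), 7 (IL-13 after pretreatment), 186 (antibody with IL-13) and 50 (change by antibody).

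Leaving out each array in turn gave 174 to 296 genes for IL-13, 2501 to 3511 for pretreatment, 1 to 45 for IL-13 after pretreatment, 210 to 377 for IL-13 after pretreatment and antibody, 0 to 2 for the antibody alone and 73 to 158 for the antibody with IL-13. The changes gave 21 to 68 by pretreatment, 18 to 42 by antibody, and 7 to 14 for the response after antibody against that without pretreatment. Arrays that moved a count by over 1.5 times were Pre_IL13 P6-A, P6-B and P8-B (2 each), P8-A, Pre_only P6-A and P6-B (1 each) and Pre_only P8-B (45) for IL-13 after pretreatment. They were Pre_only P8-B (2) for the antibody alone, Pre_IL13 P6-A (73) for the antibody with IL-13, Control P6-B (25), Pre_only P6-B (21) and Pre_only P8-B (68) for the change by pretreatment. For the change by antibody they were Pre_IL13 P6-A and Pre_only P6-A (18 each), and Pre_Ab_only P6-A and IL13 P8-A (14 each) for the response after antibody against that without pretreatment. Without an array of passage 6 or 8 that leaves an arm with 1 array, that array is assumed to vary like the other groups. The score differences ranged from 0.97 to 1.08 for IL-13, 0.66 to 0.72 for pretreatment, 0.31 to 0.42 for IL-13 after pretreatment, 0.89 to 0.95 after pretreatment and antibody, -0.05 to 0.02 for the antibody alone and 0.48 to 0.59 for the antibody with IL-13. Of 7107 values of named genes 282 lost and 4 gained a call, and of 309 values 64 lost it with median scaling, 58 with the passage term left out, 111 with the mean of A and B and 126 at 2-fold.

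For genes that rose, measured in the other passage, the means of both medians were 1.15, 0.28 and 1.01 for IL-13 without pretreatment, after it and with antibody with a selection at 2-fold. After pretreatment they were 0.14 without background correction and 0.37 with median scaling, which gave 0.94 with antibody. For genes that fell, IL-13 without pretreatment gave -0.54 without background correction and -0.62 with median scaling, and after pretreatment the sign changed to 0.01 (0.012) and 0.15. A selection of fallen genes at 2-fold gave no value. With an estimated correlation 2 lists passed for IL-13, 0 for IL-13 after pretreatment, 4 after pretreatment and antibody, 1 for the antibody alone, 2 for the antibody with IL-13, 1 and 2 for the changes by pretreatment and antibody and 0 for the response after antibody against that without pretreatment. With fry 2 passed for IL-13 after pretreatment, 1 for the antibody alone, 3 for the antibody with IL-13, 1 for the change by pretreatment and 0 for the response after antibody against that without pretreatment. Signal over background limits what dim genes such as CCL11, HAS3 and CISH can show.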

Other observations

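The genes here were chosen after their values were seen, as was the test of neighbouring genes. The fetal globin genes HBG1 (4.27 ± 0.25) and HBG2 (4.18 ± 0.23), near-identical paralogs, rose with pretreatment, and with IL-13 they had values of -0.31 and -0.46 that were not called. The alcohol dehydrogenase genes ADH1A (3.57 ± 0.39) and ADH1B (2.70 ± 0.36) and the aldo-keto reductase genes AKR1C4 (2.91 ± 0.29) and AKR1C2 (1.28 ± 0.25) rose with pretreatment, whereas ADH1C (0.30 ± 0.12, adjusted p = 0.0782) was not called. Whether the probes tell related genes of these families apart was not tested. Changes with pretreatment were smaller in passage 8. They were 4.91 in passage 6 and 1.65 in passage 8 for ADH1A, 3.81 and 1.52 for AKR1C4 and 2.11 and 0.08 for AKR1C2. The reverse held for the interleukin genes IL6 (1.99 in passage 6 and 4.00 in passage 8) and IL1B (2.05 and 4.32), and ELN, elastin, had -0.66 and 1.35. For IL6 the changes with Pre_Ab_only in place of Pre_only were 1.51 and 3.69. Its level in Pre_Ab_only was 12.278 on P8-B and 12.257 on average on the other arrays, against 9.66 ± 1.26 (SD) in Control. That passage difference of IL6 therefore lies in the Control level and not in the level reached after pretreatment and antibody.

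IL17RA, a receptor subunit for IL-17, rose with IL-13 by 1.20 ± 0.15 without pretreatment and by 0.97 ± 0.15 after pretreatment and antibody, and its response was changed by -1.03 ± 0.22 by pretreatment. With IL-13 after pretreatment and antibody the hyaluronan synthase gene HAS3 was at least 2.03-fold and IL1RL1, a receptor gene of the IL-1 family, at least 1.84-fold higher from undetected levels. HAS2 (0.48 ± 0.13) rose as well, as did IL18R1 (1.18 ± 0.14), another receptor gene of that family, and STEAP1 (1.35 ± 0.11) and STEAP2 (1.02 ± 0.15). In the same families IL1R1 (0.28 ± 0.19), IL1RAP (-0.02 ± 0.15) and STEAP3 (0.09 ± 0.11) were not called, and HAS2 had an adjusted p = 0.0498.

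Among the 30 genes with a called change of the response by antibody, 2 pairs lie next to each other among the tested genes in the order of the RefSeq table, IL1RL1, undetected in Pre_Ab_only, with IL18R1 (1.13 and 1.12) and STEAP1 with STEAP2 (1.43 and 1.04). Random draws of 30 genes gave 0.0693 such pairs on average, and a share of 0.0017 of 10000 draws gave as many. Neighbouring genes may respond together more often than chance, as a hypothesis found and tested on the same data. Both pairs are also paralogs, which keeps open that a shared origin and not position is the link.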
